A study of Homo sapiens with 12 samples.

How the data were processed

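Messenger RNA was measured by RNA sequencing in 12 libraries of K562 cells, an established human erythroleukaemia line that grows in suspension and expresses fetal and embryonic globins. The labels put 6 libraries in a group called RBM48 KO and 6 in a vector control group, each numbered 1 to 6. The titles also give same-numbered libraries of both groups a shared pair of further numbers, and all KO libraries a shared code. What these stand for is not stated. RBM48 is an RNA-binding protein of the minor spliceosome, the machinery that removes the rare U12-type introns. The labels describe total RNA extracted with Trizol, DNase treatment and stranded paired-end libraries. The treatment protocol in the labels describes a different edit, the insertion of a Myc tag at RBM48 followed by single-cell expansion, and does not describe how the knockout or the vector control cells were made. The design text speaks of triplicates, whereas 6 libraries per group are listed. Nothing in the labels says that the libraries came from separate cultures or clones, so p-values measure only the spread between these libraries, which may be technical.

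The deposited count table holds whole-number counts per Ensembl gene for each library, with no normalization. The submitters' processing notes list bcl2fastq 2.18.0.12, cutadapt 1.1, Trimmomatic 0.22, HISAT2 2.0.4, HTSeq and the GRCh38 build, without roles, and the annotation release and the strand setting of the counting are not given in the sources used here. A gene-level count adds reads over a whole gene, so retained introns, splice choices and small insertions or deletions cannot be read from it. The authors' deposited comparison table was also used. Per the file headers it gives for each gene a mean signal over all libraries, a log2 fold change with its standard error, a test score, a p-value and an adjusted p-value. A note in its header states that a negative log2 fold change means higher expression in the knockout. The authors' model settings are not given in the sources used here.

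Gene symbols, types and positions came from GENCODE release 29 on GRCh38 and a table of gene names, which covered 99.0% of the identifiers. Identifiers without an annotation held at most 0.0266% of the counts of a library. Counts were analysed in R 4.3.3 with edgeR 4.0.16: genes were kept by filterByExpr with the group, libraries were scaled by TMM, and the groups were compared by a robust quasi-likelihood test (two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. Of 58051 genes in the table, 35863 had a count in some library and 18782 were tested. Expression levels are TMM-scaled CPM, the count of a gene relative to the scaled library total, as mean ± SD over the 6 libraries of a group. Fold changes are log2 values of KO over control with standard errors (SE). Positions are on GRCh38.

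The analysis was tested on simulated counts with the means, library sizes and dispersions of these libraries, in which 200 genes were changed. For the comparison of KO with control, among 18303 genes fitted, the test recovered 4 of 67 genes changed by 1.5-fold, 19 of 67 changed by 2-fold and 48 of 66 changed by 4-fold, with 3 false calls among 74. Most changes of 2-fold or less were therefore missed at this spread of single genes between libraries. Each gene was drawn on its own, so the simulation lacks differences between libraries that many genes share. Its shares recovered and its count of false calls may not hold for the data.

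A total of 28 gene lists was written before the data were examined: U12-type intron genes, splicing machinery, red cell, megakaryocyte and other blood lineage genes, genes of adherent cells, stress responses, cell cycle, histones, mitochondrial transcripts, ribosome, nonsense-mediated decay, cholesterol, glycolysis, interferon, antigen presentation, early response, NF-kappaB, TGF-beta and mesenchymal genes, and the neighbours of RBM48. Each list was tested by camera in limma 3.58.1 on log2 CPM (prior count of 2) with a preset inter-gene correlation of 0.01, adjusted over the 28 lists. Camera with an estimated correlation, fry, and an exact permutation test of the list mean per library were run beside it, the last chosen after the data were seen. The U12-type list was a hand list of reported genes, and a motif scan of introns was not run because no genome sequence was used here. Its calls were also compared with those of other intron-holding genes by Fisher's exact test.

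The genes named in the text were fixed by rule before the data were examined: RBM48, and the 10 largest rises and 10 largest falls among called protein-coding genes with a mean of at least 5 CPM and no overlap between groups. The rule also allowed the 2 called members per direction of each list, of which there were none. The rule gave 10 genes besides RBM48, and any other gene was chosen after its values were seen. Alternatives were other scalings (RLE, library size, upper quartile), filters, DESeq2 1.42.0, limma-voom, a block on the library number, each library left out, subsets of libraries, stricter thresholds and, added after the data were seen, the omission of libraries that stood apart and surrogate variables from sva 3.50.0. Library pairs within a group were compared by chi-square over genes with a summed count of at least 20, to find libraries entered more than once. Over the 30 pairs, chi-square per degree of freedom was 18.1 to 987, so no pair lay within sampling noise and all 12 libraries were kept. The closest pairs were control libraries 3 and 4 (18.1), control libraries 5 and 6 (39.5) and KO libraries 3 and 4 (43.7). Some libraries were thus much more alike than others, for a reason the labels do not give. The group comparison nevertheless counted each library as a separate replicate.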

Results

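Transcript levels were measured in 12 RNA-seq libraries of K562 erythroleukaemia cells, 6 labelled RBM48 KO and 6 vector control. Total counts per library ranged from 90429264 in KO library 4 to 119570041 in control library 4. Between 23274 and 27510 genes had a count in a library, the 10 most abundant genes took 5.98 to 9.01% of counts, and mitochondrial transcripts took 5.01 to 6.41%.

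The targeted gene was examined first, as a check of the labels. RBM48 (ENSG00000127993, chromosome 7, 92528773 to 92538005), which encodes an RNA-binding component of the minor spliceosome, was not lower in the libraries labelled KO. Its level was 24.5 ± 3.31 CPM in KO and 22.0 ± 2.68 CPM in control libraries (SD, n = 6 each), a log2 fold change of 0.16 (SE 0.12, edgeR adjusted p = 0.9998). The fold was 1.12 with a 95% confidence interval of 0.928 to 1.34. KO libraries ranged from 20.5 to 29.1 CPM and controls from 19.9 to 26.5 CPM. The authors' deposited table gave RBM48 a log2 fold change of -0.15, which by its header note means higher in the knockout, with an adjusted p of 0.999999. A knockout made by small insertions or deletions can leave the transcript in place, so these counts neither show nor exclude loss of the protein, and every direction below is that of the libraries as labelled.

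The comparison of KO with control asked which transcripts changed in cells labelled as lacking RBM48. Few genes differed: 21 of 18782 tested genes passed the threshold, 5 higher and 16 lower in KO, and 15 of the 21 were protein-coding. SAMD5, which encodes a protein with a sterile alpha motif, was higher at 10.1 ± 1.85 CPM in KO against 2.43 ± 0.422 CPM in control (SD, n = 6 each), a log2 fold change of 2.06 (SE 0.18, edgeR adjusted p = 0.000566). GABRA2, which encodes a subunit of the GABA-A receptor, was the deepest fall among the named genes, at 0.319 ± 0.199 CPM against 11.0 ± 5.96 CPM, a log2 fold change of -5.10 (SE 0.65, edgeR adjusted p = 0.00674). SSX3, a cancer-testis antigen gene, fell from 39.5 ± 10.9 CPM to 9.25 ± 4.11 CPM, a log2 fold change of -2.10 (SE 0.28, edgeR adjusted p = 0.0103).

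RHOXF2B, a homeobox gene of the reproductive tract, was higher in KO by a log2 fold change of 1.92 (9.47 ± 2.71 against 2.50 ± 0.637 CPM). CYB5R2, a cytochrome b5 reductase gene, was higher by 1.16 (7.11 ± 1.05 against 3.19 ± 0.627 CPM). Among the lower genes, ROBO2, a receptor of Slit guidance ligands, had a log2 fold change of -1.30 (8.54 ± 2.05 against 21.1 ± 4.94 CPM). SYTL4, an effector of Rab GTPases in secretory granule release, had -1.20 (5.26 ± 1.31 against 12.1 ± 1.25 CPM), and FAM171A1 had -1.11 (6.75 ± 1.49 against 14.6 ± 1.64 CPM). PGR, the progesterone receptor gene, had -0.95 (6.92 ± 0.821 against 13.3 ± 1.86 CPM). CERS6, a ceramide synthase gene, had the highest expression of the called genes and changed least, by -0.74 (28.2 ± 3.04 against 47.0 ± 5.78 CPM). The edgeR adjusted p of these 7 genes was between 0.00563 and 0.0220. In each of the 10 named genes, all 6 KO libraries lay on the same side of all 6 controls, as the naming rule required. SSX3 and RHOXF2B have near-identical copies on the X chromosome, so the assignment of their counts is uncertain.

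**Figure D1:**
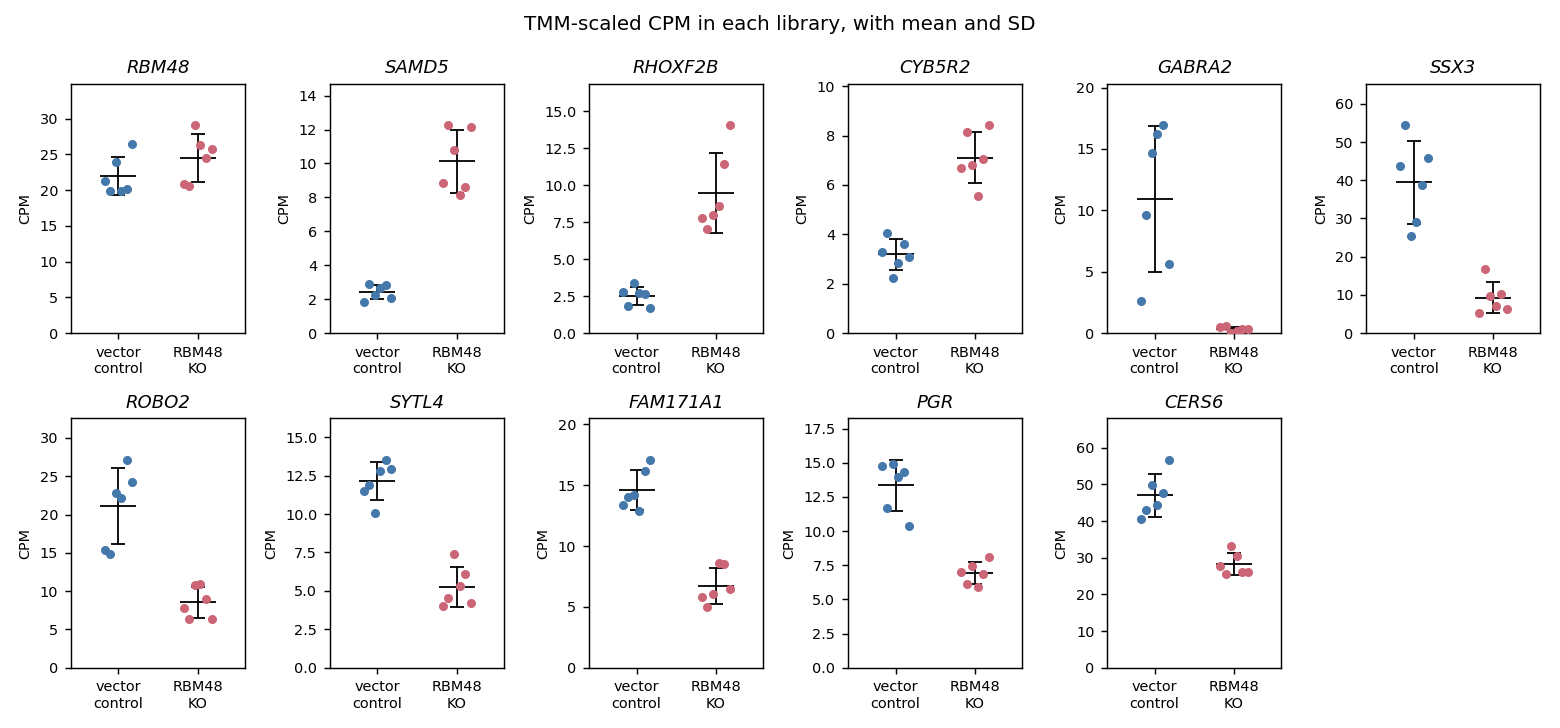
TMM-scaled CPM (vertical axis, from 0) of RBM48 and the 10 named genes in each library (points), with the mean (long bar) and SD (error bars) of the 6 libraries per group. RBM48 overlaps between groups at 24.5 and 22.0 CPM. The other genes show no overlap, as the rule that named them required, with GABRA2 at 0.319 CPM in KO and 11.0 CPM in control.

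The named genes lie on several chromosomes. SAMD5 (ENSG00000203727) spans 147508927 to 147737547 on chromosome 6, CYB5R2 (ENSG00000166394) 7665100 to 7677222 on 11, and PGR (ENSG00000082175) 101029624 to 101130524 on 11. GABRA2 (ENSG00000151834) spans 46248427 to 46475230 on 4 and ROBO2 (ENSG00000185008) 75906695 to 77649964 on 3. FAM171A1 (ENSG00000148468) spans 15211643 to 15371062 on 10 and CERS6 (ENSG00000172292) 168455862 to 168775137 on 2. On X lie RHOXF2B (ENSG00000203989, 120070672 to 120077705), SSX3 (ENSG00000165584, 48346428 to 48356707) and SYTL4 (ENSG00000102362, 100674491 to 100732123). The other 11 called genes fell outside the naming rule because they averaged below 5 CPM or were not protein-coding. POF1B (log2 fold change 3.61) and PLAAT1 (2.39) were higher, and BCHE, the butyrylcholinesterase gene, was the deepest fall of all called genes at -6.21 (0.0330 ± 0.0396 against 2.58 ± 1.72 CPM). ANKRD62 (-3.21) and GALNTL6 (-2.13) were also lower, as were the pseudogene DPY19L2P1 (-3.16), the long non-coding RNA LINC01515 (-4.02) and 4 genes known by identifier alone, at -2.37 to -3.15.

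All 21 called genes showed no overlap between the groups, as did 105 tested genes (0.559%), where 0.216% is given by chance. At an unadjusted p below 0.05 there were 558 genes by edgeR, against 939.1 given by chance. With the library number as a block there were 1360. With 2 surrogate variables, whose p-values may be too small, there were 2295. The shortfall against chance therefore depends on the model and does not show that the groups are alike. The authors' deposited table called 98 genes, 39 higher and 59 lower in the knockout by its header note, and all 21 genes called by edgeR were among them in the same direction. The count moved with the libraries and the model: without KO library 5 or 6 it was 12 or 7, and without control library 3, 4, 5 or 6 it was 9, 7, 7 or 10. Replicates 1 to 3 alone gave no edgeR call, with 127 genes at an unadjusted p below 0.05. With the library number as a block edgeR called 43 genes. Chosen after the data were seen, the omission of library 2 of both groups and KO library 1 gave 39 and 2 surrogate variables gave 200. DESeq2, which tested 25142 genes under its own filter, called 112, so the tool and the set of genes changed together. The authors' comparison, labelled as DESeq2, gave 98 calls among 18298 genes with an adjusted p. A larger set of genes is thus not needed for a higher count, although the authors' settings are unknown.

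Because RBM48 acts in minor splicing, genes reported to hold a U12-type intron were compared with other genes. None of the 28 genes of the list was called by edgeR, DESeq2 or limma-voom, with 18 above and 10 below a log2 fold change of 0 and a median of 0.05. At an unadjusted p below 0.05, 2 members were higher and none was lower, and none was called when adjusted over the list alone. Camera did not separate the list from other genes (adjusted p = 0.363, and 0.634 with an estimated correlation). Among 16089 other genes with an intron, 5 were called higher and 15 lower, so few that counts of calls could not tell 28 genes from the others. BRAF, a kinase gene with a U12-type intron, stood at 74.4 ± 9.14 CPM in KO and 84.3 ± 12.1 CPM in control (SD, n = 6 each). E2F5, a cell cycle transcription factor gene, stood at 15.5 ± 2.45 and 16.8 ± 2.06 CPM. Both means were lower in KO, whereas 18 of the 28 members lay above 0. These examples, chosen after their values were seen, do not stand for the list. Among 15 proteins of the minor spliceosome and RBM48 partners the median log2 fold change was 0.04, and among 46 core proteins of the major spliceosome it was 0.05, with camera adjusted p of 0.913 and 0.513. These are gene-level counts, which do not measure whether an intron was retained.

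The remaining lists asked whether other programmes of these cells differed. Of 650 tested members of the 28 lists, none was called by edgeR over all genes, with 12 at an unadjusted p below 0.05. DESeq2 called 2 of them, SPARC and CA2, and limma-voom called 0. When adjusted over the list alone, 2 were higher and 0 lower: SPARC, a matrix glycoprotein gene, in the TGF-beta and mesenchymal list (40.6 ± 8.52 CPM in KO against 22.5 ± 3.94 CPM in control, log2 fold change 0.85), and CA2, a carbonic anhydrase gene, in the erythroid list (2.01 ± 0.971 against 0.350 ± 0.229 CPM, log2 fold change 2.52). Over all genes edgeR gave SPARC an adjusted p of 0.0850 and CA2 an adjusted p of 0.110.

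Camera called 4 lists. The TGF-beta and mesenchymal list was higher in KO, with 12 of 16 members above 0, a median log2 fold change of 0.34 and an adjusted p of 0.000806, or adjusted p = 0.254 with an estimated correlation. Besides SPARC, its member ID2, an inhibitor of DNA-binding transcription factors, stood at 13.2 ± 3.09 CPM in KO against 7.79 ± 2.41 CPM in control. VIM, the vimentin gene, stood at 1454 ± 512 against 1172 ± 383 CPM. Both genes overlapped between the groups (edgeR adjusted p = 0.824 and 0.9998), and 4 members of the list lay below 0. Ribosomal protein genes were higher, with all 76 above 0, a median of 0.13 and an adjusted p of 0.00152, or adjusted p = 0.968 with an estimated correlation. Early response genes were higher, with 19 of 20 above 0, a median of 0.28 and an adjusted p of 0.00327, or adjusted p = 0.597 with an estimated correlation. ATF4 targets of the integrated stress response were lower, with 22 of 28 below 0, a median of -0.15 and an adjusted p of 0.00327, or adjusted p = 0.968 with an estimated correlation. None of the 28 lists was called with an estimated correlation or by fry. The exact permutation test (two-sided) of the mean per library gave the TGF-beta and mesenchymal list p = 0.0130 before adjustment. The exact permutation p was 0.654 for ribosomal protein, 0.342 for early response and 0.727 for stress response genes, also before adjustment. The smallest p this test can give is 0.00216, with which a single list could not pass the threshold over 28 lists. The absence of calls by it therefore says little about the TGF-beta and mesenchymal list. The other lists called by camera lay far above this smallest p, so the exact permutation test gave no sign of a group difference in them.

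In 3 of these 4 lists the call was lost when a single library was left out. With all libraries the mean log2 fold change over the members was -0.14 for the stress response, 0.28 for the early response and 0.15 for the ribosomal protein list. Without KO library 1 the mean was 0.04 for the stress response and 0.02 for the early response list, and neither was called. Without control library 2 their means were -0.03 and 0.29, and neither was called, although the early response mean was no lower than with all libraries (adjusted p = 0.0576). The early response list was called in replicates 4 to 6 alone (mean 0.27, adjusted p = 0.00108) and without library 2 of both groups (mean 0.27, adjusted p = 0.0204). Without KO library 2 the ribosomal protein list had a mean of -0.05 and was not called. The TGF-beta and mesenchymal list stayed called by camera in all 25 alternative settings with the preset correlation, with means of 0.26 to 0.42.

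The other 24 lists had medians between -0.06 and 0.18 and camera adjusted p of 0.111 to 0.966. In the erythroid list, 39 members were tested with a median of 0.03, and in the haem synthesis list 9 members with a median of 0.15. Their means were 0.14 and 0.13, and without KO library 2 both lists were called, with means of 0.28 (camera adjusted p = 0.000397) and 0.18 (adjusted p = 0.0448). HBG2, a fetal globin gene abundant in K562, stood at 936 ± 518 CPM in KO and 970 ± 567 CPM in control, although its near-identical copy HBG1 makes the assignment of counts uncertain. Megakaryocyte genes had a median of 0.09. Markers of other cell types had medians of 0.10 for myeloid, 0.18 for lymphoid and 0.08 for adherent cell genes. DNA replication genes had a median of 0.09, mitosis genes -0.06, histone genes 0.10 and p53 targets 0.01. The DNA replication list was called in 10 of 25 alternative settings, with means of 0.08 to 0.17, against a mean of 0.09 and an adjusted p of 0.111 with all libraries. In all, 13 of these 24 lists were called in at least 1 alternative. Unfolded protein response genes had a median of 0.08, heat shock genes 0.12, ribosome assembly factors 0.10 and genes held low by nonsense-mediated decay 0.10. Cholesterol genes had a median of 0.11, glycolysis genes 0.06, interferon-stimulated genes -0.02, antigen presentation genes 0.08 and NF-kappaB targets 0.05. Mitochondrially encoded transcripts had a median of 0.05, and the neighbours of RBM48 -0.06. Camera placed the unfolded protein, antigen presentation and mitochondrial lists downward, opposite to their medians.

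The libraries differed more among themselves than by group. The leading principal component held 41.0% of the variance and the next 24.1%, and neither separated KO from control (exact permutation p = 0.944 and 0.621, two-sided). The component after these held 7.93%, with an exact permutation p of 0.0216 that became 0.130 when adjusted over 6 components. Library 2 of each group lay at one end of the leading component, with scores of 98.7 in KO and 101.4 in control. KO library 1 lay at the other end at -95.1, so this component is not an effect of library 2 alone. In library 2 the endoplasmic reticulum chaperone gene HSPA5 stood at 6908 CPM in KO and 5614 CPM in control, and in the other libraries at 816 to 1479 CPM. HBG2 stood at 289 and 182 CPM in the same libraries and at 418 to 1619 CPM in the others. KO library 1 had the asparagine synthetase gene ASNS at 340 CPM, where the other 11 libraries had 1037 to 1503 CPM. EGR1, an early response gene, stood at 724 CPM in KO library 1 and 608 CPM in control library 1.

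**Figure D2:**
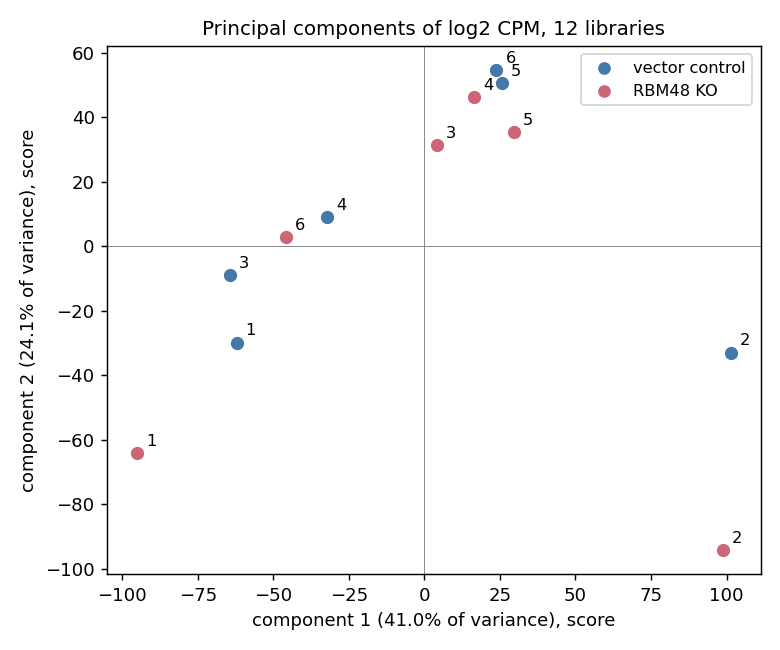
Scores of the 12 libraries on the leading principal components of log2 CPM (41.0% of variance on the horizontal axis, 24.1% on the vertical axis), coloured by group and numbered as in the labels. Library 2 of both groups lies at the far right, at 98.7 and 101.4, and KO library 1 at the far left, at -95.1. The groups overlap on both axes.

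**Figure D3:**
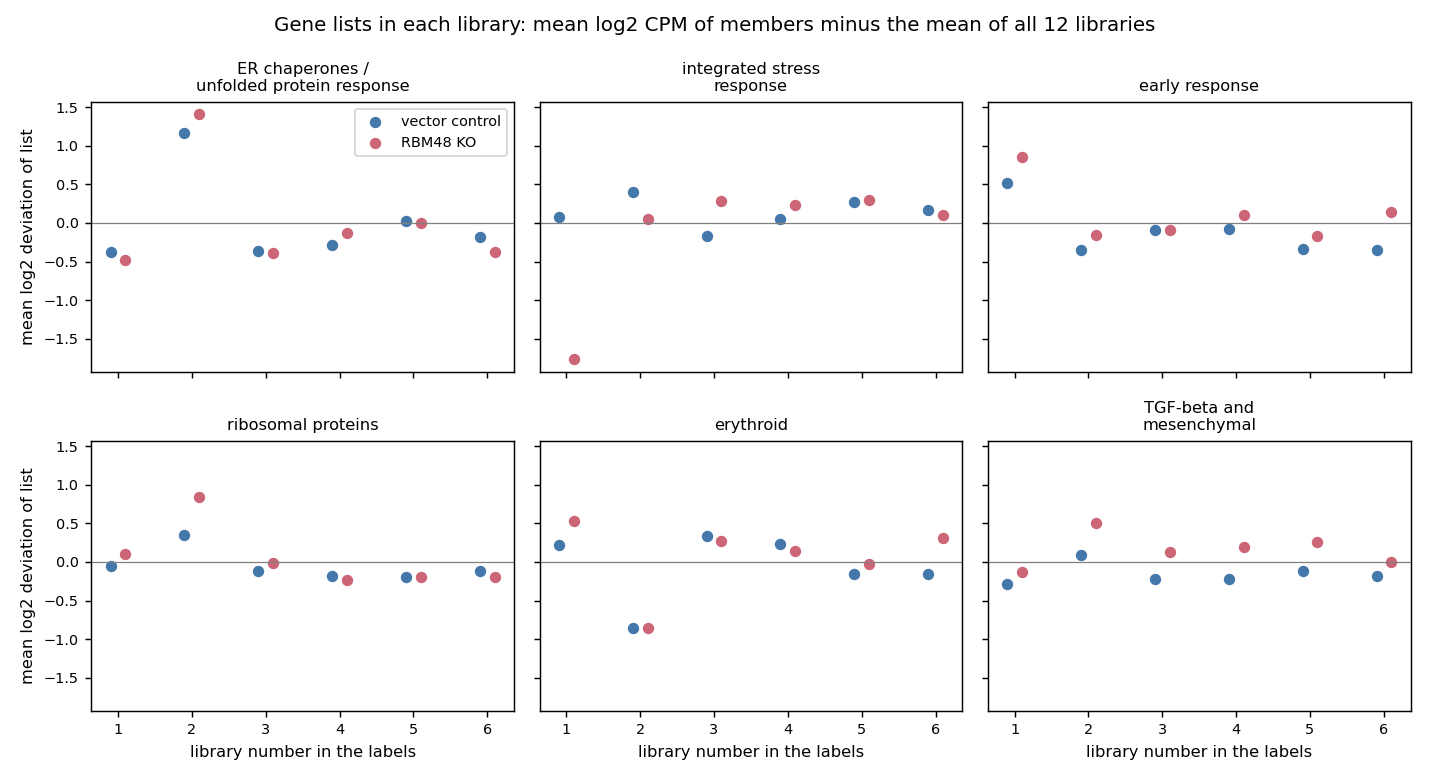
Mean log2 deviation of 6 gene lists from their mean over all 12 libraries (vertical axis), by library number (horizontal axis) and group (colour). Endoplasmic reticulum chaperone genes deviate by 1.41 and 1.16 in library 2 of KO and control, and integrated stress response genes by -1.77 in KO library 1.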

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

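The tests of scaling, GC content and gene length in this part were chosen after the result was seen. The results below stood apart because a library lay far from the others of its group by Dixon's criterion. In all, 10 of 80 groups of values did so, where chance gives about 4.

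Library 2 of both groups stood apart in the same lists. Genes of endoplasmic reticulum chaperones and the unfolded protein response deviated from the mean of all libraries by 1.41 on the log2 scale in KO library 2 and by 1.16 in control library 2, with all 20 members above their mean in both. Ribosomal protein genes deviated by 0.85 and 0.35, haem synthesis genes by -0.24 and -0.23, and megakaryocyte genes in control library 2 by -0.90. Early response genes deviated by 0.85 in KO library 1 and 0.52 in control library 1. Integrated stress response genes deviated by -1.77 in KO library 1.

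The values argued against a trend with GC content or gene length as the source of the chaperone pattern, and could not test scaling. Scaling of the libraries would move the median gene as much. The list exceeded the median gene of its own library by at least 1.15 on the log2 scale, but TMM had already aligned the typical gene between libraries. The scaling check could therefore hardly have failed, and no conclusion is drawn from it. A trend with GC content or gene length would be removed by a smooth fit within each library, but after it the deviation was at least 1.099 in both libraries. A shared culture, stress or preparation of the libraries with the same number stays open, because the labels do not say what the number stands for. The groups of the study do not part these libraries, so no biological explanation was tested.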

How the results depend on the processing

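The surrogate variables and the omission of library 2 of both groups, alone or with KO library 1, were chosen after the data were seen. The surrogate variables were estimated from the same libraries, so adjusted p-values and counts of calls with them may be too favourable. The count of 21 called genes was 18 to 23 under other scalings, 20 without a filter and 17 with a filter of at least 1 CPM in 6 libraries, and limma-voom gave 21. It moved to 112 with DESeq2, which tested 25142 genes where edgeR tested 18782 (47 higher, 65 lower, all 21 kept), to 6 at an adjusted p below 0.01, to 0 in replicates 1 to 3, to 11 in replicates 4 to 6 (9 of the 21 kept) and to between 7 and 25 when a library was left out. It was 27 without library 2 of both groups, 39 when KO library 1 was left out as well, and 200 (87 higher, 113 lower, all 21 kept) with 2 surrogate variables. The cause was not tested, except that fewer libraries entered the subsets. Deviations of same-numbered libraries correlated above 0.1 in 3 of 6 pairs (-0.23 to 0.76). In each group, 3 of 6 libraries correlated best with their own number. The rule set beforehand asked for all 6 pairs, so the numbers were not taken to pair the samples. A link within some of the pairs stays open. With the number as a replicate block, 43 genes were called, including all 21.

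SAMD5, RHOXF2B, GABRA2 and SSX3 passed the threshold in 24 of 25 settings, SYTL4 in 18, PGR in 17, FAM171A1 in 16, CERS6 and ROBO2 in 15 and CYB5R2 in 14. None changed sign. The naming rule asked for no overlap between groups, so the sign could hardly have changed and its stability is no support. RBM48 stayed at 0.11 to 0.24 in 25 settings (lowest adjusted p 0.411) and the U12-type list at a mean log2 fold change of 0.03 to 0.09 in 27 settings (lowest adjusted p 0.118). The motif scans for U12-type introns and the summing of duplicates were not run.

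The number of lists called by camera was 3 to 10 with a library left out, and 0 with an estimated correlation or fry. With each library left out, the mean log2 fold change of a list ranged from -0.067 to 0.11 for the major spliceosome, -0.19 to 0.041 for the stress response, -0.37 to 0.48 for the unfolded protein response, -0.048 to 0.26 for ribosomal proteins, -0.16 to 0.25 for ribosome assembly and -0.24 to 0.26 for cholesterol genes. In replicates 4 to 6, these means were 0.053 for the stress response, -0.16 for mitochondrial transcripts and -0.040 for ribosomal proteins. Without library 2 of both groups and KO library 1 they were -0.16 for the major spliceosome, 0.12 for the stress response, -0.26 for heat shock, -0.021 for ribosomal proteins, -0.20 for ribosome assembly and -0.047 for early response genes. With surrogate variables the unfolded protein response had -0.11, and the erythroid and haem synthesis lists were called (0.20, adjusted p = 0.0155, and 0.15, adjusted p = 0.0161). The cause was not tested. Depth limits genes with few counts, such as GABRA2, which had 2 to 52 counts in the KO libraries.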

Other observations

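The tests on the X chromosome and the values with surrogate variables in this part were chosen after the data were seen. With 2 surrogate variables in the edgeR model, 200 genes were called, among them members of the lists. These variables were estimated from the same libraries with the group kept in the model, and were then treated as known. The adjusted p-values from this model may therefore be too small. CA2 was higher in KO (log2 fold change 2.41, adjusted p = 0.000845), as was CD36, a platelet and fatty acid receptor gene (0.97, adjusted p = 0.0271), and GP6, the platelet collagen receptor gene, was lower (-0.81, adjusted p = 0.00556). SPARC was higher (0.84, adjusted p = 0.0151), as was the early response gene SPRY4 (0.37, adjusted p = 0.0360). GATD3, on the U12-type list, was higher (0.41, adjusted p = 0.0199), against 0 other called members of the 28. CDK6, the cell cycle kinase gene beside RBM48 on chromosome 7, was lower (-0.26, adjusted p = 0.0384). Without the surrogate variables edgeR called none of these genes and DESeq2 called CA2 and SPARC, and CDK6 stood at 194 ± 36.8 CPM in KO and 236 ± 37.1 CPM in control (SD, n = 6 each). Chosen after its values were seen, SLIT2, which encodes a ligand of ROBO2, was lower in the same model (-1.47, adjusted p = 1.45e-05), as was ROBO2 itself (-1.21, adjusted p = 0.000218). Without the surrogate variables edgeR did not call SLIT2 (-1.50, adjusted p = 0.9998) but called ROBO2.

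The number of called genes was set against other splits of the 12 libraries into 6 and 6. Of 100 of the 462 distinct splits, 4 gave at least 21 calls, the real one included, a share below 0.05. This margin is so narrow that a draw of 100 does not settle the share of all 462, so chance is not firmly excluded. The splits were drawn without regard to the library number. The highest other split gave 4085 calls, and 96 of the others gave none. The split with 4085 calls put KO libraries 1, 3 and 6 with control libraries 1, 3 and 4, so it follows the structure of the leading principal component and not the groups. Copy number change of the regions that hold the called genes may be weighed as a cause: it predicts that neighbouring genes shift too. The median of the 20 nearest expressed genes, signed by the direction of the called gene, was 0.026 over the 21 genes (95% bootstrap interval 0.016 to 0.048, highest 0.11), which argues against broad gains or losses. Called genes were left out of the neighbours, and a change of a few adjacent genes would move this median little. A change of a single gene or of a few genes therefore stays open. So does a difference between founder cells that was already present before any edit, since the labels do not give the clones behind each group.

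Of the 21 called genes, 4 lie on X (POF1B, RHOXF2B, SSX3 and SYTL4), or 19.0% against 3.68% of the other tested genes. Fisher's exact test (two-sided) gave p = 0.00670, or 0.154 when adjusted over 23 chromosomes, so an excess on X may be proposed but is not decided by 21 genes. A gain or loss of a whole active X chromosome predicts a shift of most of its genes. The check took the 380 X-linked genes that passed an expression cut-off and were not called. Their median log2 fold change lay only -0.0026 from that of the other genes above the same cut-off (95% bootstrap interval -0.02 to 0.01). A gain or loss of an inactive X would move this median little, so it stays open. ANKRD62 and the pseudogene ENSG00000267733 are neighbours on chromosome 18 and both were lower, at -3.21 and -2.41. Their nearest expressed genes, with called genes left out, had a median of -0.02, so a small change that spans both genes stays open.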
